A study of Moxostoma hubbsi with 18 samples.

How the data were processed

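RNA was measured by high-throughput sequencing in 18 libraries from larvae of the copper redhorse (Moxostoma hubbsi), an endangered freshwater fish of the sucker family. Each library came from a pool of 5 whole larvae aged 14 days after fertilization, so each value is a sum over all tissues of several animals. Per the labels' protocols, larvae were frozen on dry ice, total RNA was extracted with an RNeasy kit and DNase treatment, and libraries followed standard Illumina procedures. Samples were grouped by the water named in their titles, with 9 libraries of laboratory water (the control) and 9 libraries of river water.

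The deposited files hold whole-number counts per feature for each library, with no normalization. The aligner, the sequence database and the counting program are not given in the sources used here. The submitters' processing notes name edgeR and no version. Features carry identifiers made of a K and 5 digits, the form that KEGG uses for groups of orthologous genes. If a feature pools related genes in that way, opposite changes of paralogs can be hidden in its count. The files do not pair the identifiers with gene names or positions, and no reference table was used here. Gene names, genome positions, gene length and GC content were therefore not analysed here, and at most 2 identifiers per direction are printed. For the same reason, 30 gene lists fixed before the data were examined could not be matched to features, and neither the list tests nor the counts of list members were run.

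Each sample file lists 9025 features. A table of the whole series lists 9645 features, and 0 values of the sample files differ from it. The 620 features found in the series table alone have at most 1446 counts each over the 18 libraries and 0.0215% of all counts. The sample files were used for the main results, and the series table served as an alternative, with its columns assigned to groups by its own class line. It held 0 columns of per-sample values that went unused.

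Depth was between 14868181 and 20584727 counts per library, and 9019 to 9025 of the listed features had at least 1 count in a given library. All pairs of libraries differed by more than sampling noise (chi-square per degree of freedom at least 4.21), so none was treated as a repeat deposit. The labels do not say whether the 9 samples of a group came from separate tanks or families. The p-values measure the spread between these pools, which may be partly technical.

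Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features passed the default low-count filter of edgeR (a minimum count of 10, a minimum total of 15), which removed 17 and left 9008. Libraries were scaled by the trimmed mean of M values (TMM), and the water groups were compared with edgeR's quasi-likelihood F test with robust estimation and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. All 18 libraries entered 1 fit with the water as the only term. Fold changes are log2 of river over laboratory water. The standard error is the log2 fold change divided by the square root of its F statistic. Levels are CPM, counts divided by the TMM-scaled library size and brought to a common total, and log2 CPM used a prior count of 2. Library similarity was described by Spearman correlation and principal components of log2 CPM.

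The rule for naming features took, among those past the threshold with a mean log2 CPM of at least 1, the largest rises and falls. It was set at 6 per direction before the data were examined. It was shortened to the first 2 per direction because the files give no gene names and no reference table was used. Its parts that rest on gene names could not be applied.

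The fit was tested on simulated data with the real means, library sizes and dispersions. Each feature was drawn independently, so the rates below do not cover libraries in which many features shift together. The numbers of features changed 1.2-fold, 1.5-fold and 2-fold were 67, 67 and 66. Recovery after adjustment depends on the share of features changed, so the rates need not hold for the real data. In that simulation of river against laboratory water over 9008 features, edgeR recovered 35.8% of features changed 1.2-fold, 89.6% of those changed 1.5-fold and 98.5% of those changed 2-fold, with 7 false calls among 156. DESeq2 made 15 false calls among 171 and limma-voom 8 among 160.

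Alternatives fixed before the data were examined were other scalings, other low-count filters, DESeq2 1.42.0, limma-voom (limma 3.58.1), a fit without robust estimation, the replicate number as a block, 3 treatments of a number from 1 to 3 in the names of the deposited files (as a block, as a source of correlation within a group, or by summing its 3 libraries), a fold-change minimum of 1.5, and leaving out each library. The meaning of that file number is not stated in the labels. Alternatives chosen after the data were examined were the omission of river water replicates 1 and 6 together, limma-voom with quality weights, the whole series table, a covariate taken from the laboratory water libraries, and 4 other settings of the similarity measure. Same-numbered samples of the 2 groups were not treated as pairs, since the labels give the numbers no shared origin.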

Results

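The transcriptomes of whole copper redhorse larvae were profiled at 14 days after fertilization, following rearing in laboratory water or in river water. Each group held 9 libraries, each from a pool of 5 larvae. Total counts were between 15893484 and 20584727 in laboratory water and between 14868181 and 20095604 in river water. Counts were assigned to 9025 features, of which 9008 were abundant enough to test. The 20 most abundant features held 30.4% to 32.5% of the counts in the laboratory water libraries. In 8 of the river water libraries their share was 28.0% to 33.6%, and in river water replicate 1 it was 37.6%.

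The similarity of the libraries was examined before the groups were compared. River water replicate 1 stood apart from the rest. Its Spearman correlations with the other 17 libraries were 0.928 to 0.965, whereas the 136 pairs of other libraries correlated at 0.982 to 0.997. Against the mean of the other river water libraries, 757 features were more than 2-fold lower and 86 more than 2-fold higher in this library. River water replicate 6 was the next most distant, with 157 features more than 2-fold higher and 1 more than 2-fold lower than the mean of the others. That mean includes river water replicate 1. Against the mean of the other 7 river water libraries, 85 features were more than 2-fold higher in replicate 6. The remaining 16 libraries each had between 3 and 26 features more than 2-fold from the mean of all others of their group. River water replicate 1 also had the lowest total count, 14868181.

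**Figure D1:**
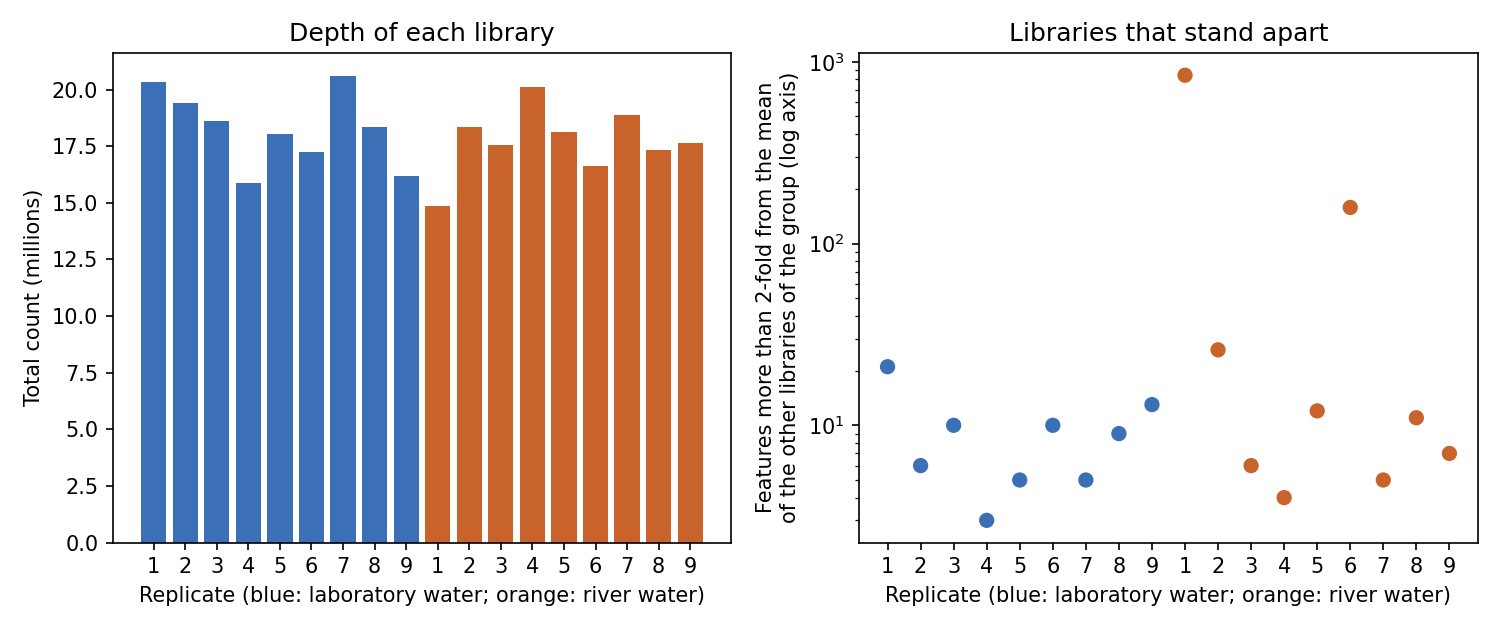
Left, total count of each library; right, the number of features more than 2-fold from the mean of the other libraries of the same water group, on a log axis, with 1 bar or point per library (blue, laboratory water; orange, river water). River water replicates 1 and 6 lie at 843 and 158 features, above the 3 to 26 of the other libraries. All totals lie between 14868181 and 20584727. The mean used for replicate 6 includes replicate 1. Against the mean of the other 7 river water libraries, 85 features were more than 2-fold higher in replicate 6.

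The first principal component of all 18 libraries held 50.6% of the variance, with river water replicate 1 alone at its far end. The second component held 12.8% of the variance, and on it the 9 river water libraries did not overlap with the 9 laboratory water libraries. Once river water replicate 1 was left out, none of the first 4 components separated the groups completely.

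The comparison that the design implies asks which transcripts differed between larvae raised in river water, which the series title describes as contaminated, and larvae raised in laboratory water. In river water 192 features were higher and 373 were lower at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 9 libraries per group), which made 565 of the 9008 tested. Most changes were small. The median change was 1.21-fold among the higher features, and among the lower features the median level in river water was 0.824 times that in laboratory water. A change of at least 1.5-fold was found for 46 of these features, of which 25 were higher and 21 lower. At least a 2-fold change was found for 9 of the 565 features, of which 8 were higher and 1, K01298, was lower. The number was 14 without river water replicate 2 and 18 without river water replicate 6. The 8 features that at least doubled rose between 2.02-fold and 5.86-fold. Over all tested features the median log2 change was 0.01.

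The changed features made up a small part of the RNA counted. The 192 higher features held 1.37% ± 0.0311 (SD, n = 9) of the counts in laboratory water and 1.72% ± 0.0601 (SD, n = 9) in river water. The 373 lower features held 3.92% ± 0.0597 (SD, n = 9) of the counts in laboratory water and 3.37% ± 0.262 (SD, n = 9) in river water. These features were chosen on the same libraries, so the shares describe their size and are not separate evidence of their direction. Of the 20 most abundant features 0 passed the test with edgeR, DESeq2 or limma-voom, and 3 had an unadjusted p under 0.05 (edgeR). Their log2 changes were between -0.47 and 0.24. With the tested features ranked by abundance and divided into 3 parts, 8.13% changed in the most abundant part, 6.23% in the middle part and 4.46% in the least abundant part. The median size of the log2 change among changed features was 0.23, 0.26 and 0.42 in the same order. Deeper counts make smaller changes detectable, and the difference between the parts was not tested.

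**Figure D2:**
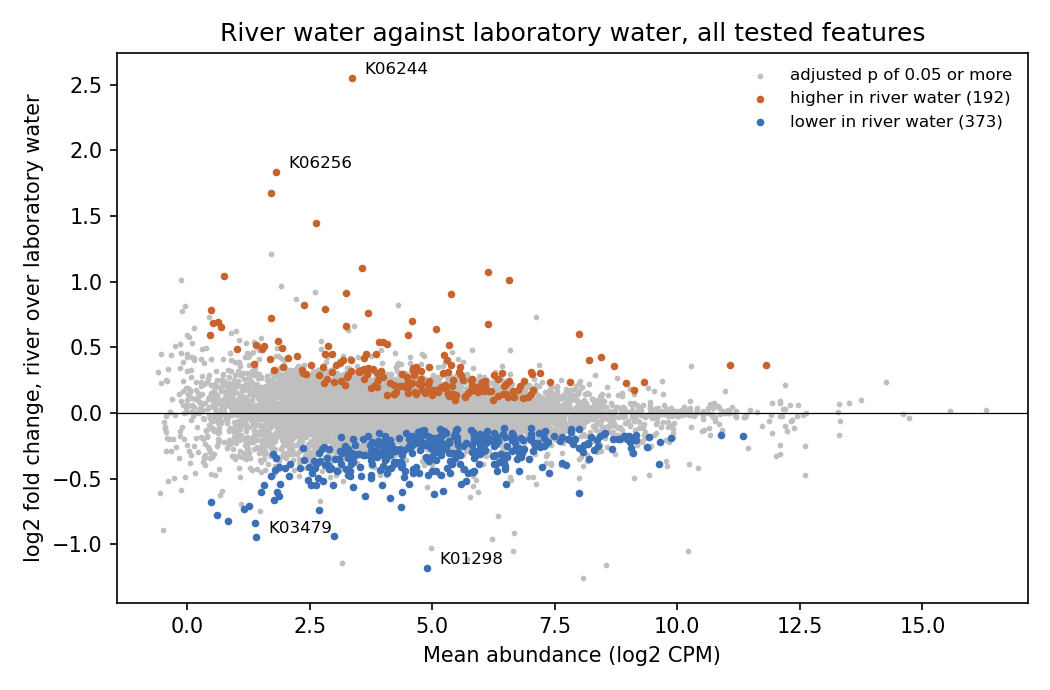
Log2 fold change of river over laboratory water (vertical axis) against mean abundance in log2 CPM (horizontal axis) for the 9008 tested features; grey points did not pass an adjusted p of 0.05, orange points were higher and blue points lower in river water. The 192 higher features include 8 that at least doubled, while 1 of the 373 lower features, K01298, fell at least 2-fold.

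The largest rise was that of K06244. Its normalised level was 3.0 ± 1.81 CPM in laboratory water and 17.2 ± 15.5 CPM in river water (SD, n = 9 each), a log2 fold change of 2.55 ± 0.43 (SE) with an adjusted p of 0.00224 (edgeR). It was above the laboratory mean in 9 of 9 river water libraries. The groups overlapped, with a lowest river water level of 6.15 CPM and a highest laboratory water level of 6.75 CPM. This feature and those named below were chosen on the same libraries, so such counts describe them and are not separate evidence. River water replicate 6 had the highest level, 56.4 CPM, and without this library the river water mean was 12.3 ± 5.20 CPM (SD, n = 8) and the log2 fold change was 2.07.

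The next largest rise was that of K06256, with 1.5 ± 0.364 CPM in laboratory water and 5.33 ± 6.22 CPM in river water (SD, n = 9 each). Its log2 fold change was 1.83 ± 0.46 (SE), with an adjusted p of 0.0228 (edgeR). River water replicate 6 again had the highest level, 21.6 CPM. Without it the river water mean was 3.30 ± 1.32 CPM (SD, n = 8) and the log2 fold change was 1.14, with an adjusted p of 0.00679 (edgeR). The call was lost with limma-voom (adjusted p = 0.0557, or 0.0526 with a correlation within the file prefix) and when libraries were summed by file number (adjusted p = 0.0833, edgeR). Over the other 12 settings the adjusted p was between 0.0011 (DESeq2) and 0.0321 (edgeR), and with 1 library left out it was at most 0.0439 (edgeR).

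Among the features that passed the test and the abundance minimum, K01298 had the largest fall, from 41.0 ± 13.1 CPM in laboratory water to 18 ± 10.7 CPM in river water (SD, n = 9 each). Its log2 fold change was -1.18 ± 0.29 (SE), with an adjusted p of 0.0214 (edgeR). All 9 river water libraries were below the laboratory mean, with values from 4.01 to 36.8 CPM against 25.0 to 68.2 CPM in laboratory water. K03479 was next among the features that passed, with 3.30 ± 0.760 CPM in laboratory water and 1.69 ± 0.751 CPM in river water (SD, n = 9 each). Its log2 fold change was -0.95 ± 0.21 (SE), with an adjusted p of 0.0112 (edgeR). Its counts were low, between 6 and 88 per library.

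**Figure D3:**
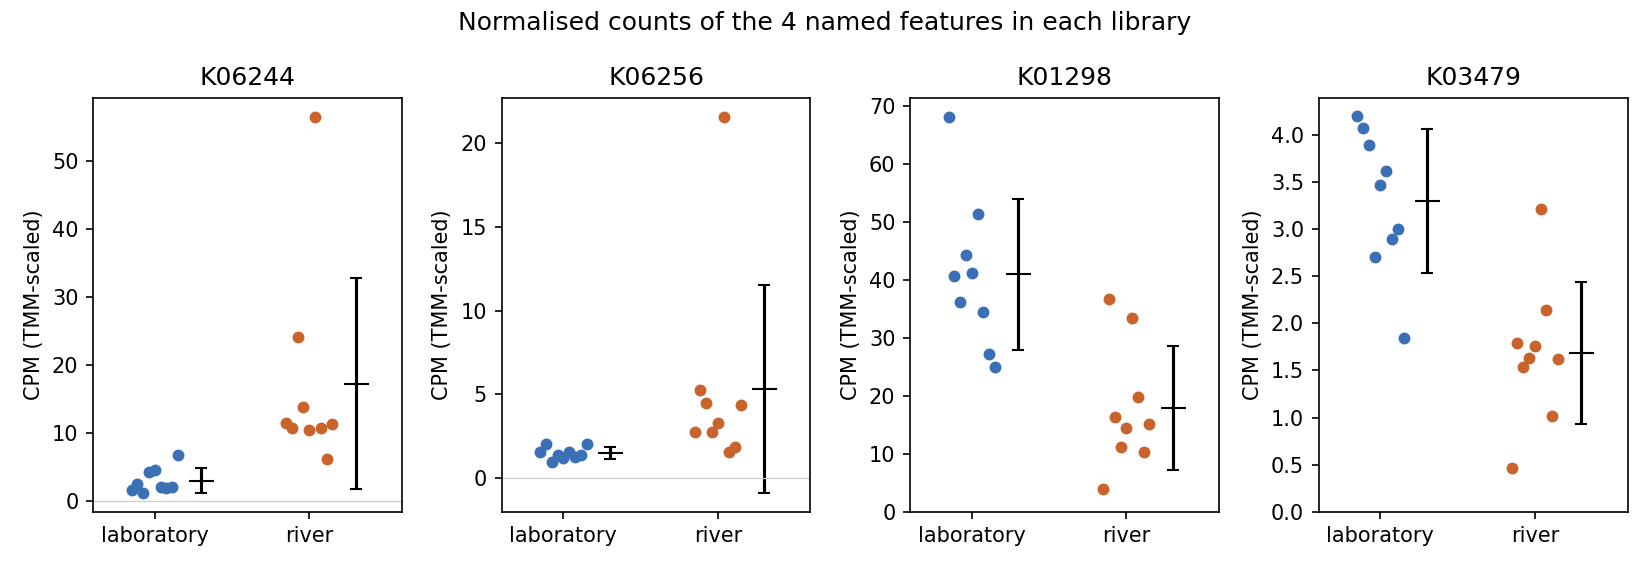
Normalised level in CPM of the features with the 2 largest rises (K06244, K06256) and the 2 largest falls (K01298, K03479) among those that passed the test and the abundance minimum, with 1 point per library (blue, laboratory water; orange, river water) and the mean and SD of each group of 9 in black. River water replicate 6 is the highest point for K06244 (56.4 CPM) and for K06256 (21.6 CPM).

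For 80 features the 9 river water libraries lay entirely above or entirely below the 9 laboratory water libraries, and 77 of these were among the 565. If all 18 libraries are independent, chance alone would separate the groups in this way for 0.0041% of features. The rate would be higher if libraries with the same number in their file names shared a tank or family, which the labels do not state.

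River water replicate 1 was left out as a check, because it differed so widely from the rest. The count then rose from 565 to 979 features, with 373 higher and 606 lower in river water, and 561 of the 565 were called again. Leaving out any other single library gave between 377 and 638 features. The number of higher features fell from 192 to 125 without laboratory water replicate 2, 121 without laboratory water replicate 3 and 119 without river water replicate 9. With river water replicates 1 and 6 both left out, 1041 features were called, 540 of them shared with the 565. With all 18 libraries, DESeq2 called 899 features, and limma-voom with quality weights called 1225.

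The names of the deposited files carry a number from 1 to 3 that could mark a batch, and the comparison was repeated within each. Summing the 3 libraries of each number and group left 311 features. If the number marked a shared tank or family, the libraries of a number would not be independent and 311 would be the applicable count, but its meaning is not stated in the labels. The correlation estimated across features within a number and group was -0.00735, and limma-voom with that correlation called 624 features. This pooled value does not show that libraries of a number are independent. Deviations from the laboratory mean correlated at a mean of 0.00657 in 9 pairs of the same number and -0.167 in 27 other pairs. In river water the corresponding means were -0.0416 and -0.0752. Deviations from a shared mean correlate negatively on average even among unrelated libraries, so a value near 0 does not show a lack of resemblance. Pairs of the same number had the higher mean in both waters, and this difference was not tested. Within laboratory water 88 features differed by file number (edgeR), and 3 of 100 partitions into trios, the file number included, gave as many. With 3 libraries per group, 0 features passed within number 1 (642 at an unadjusted p under 0.05, edgeR), 5 within number 2 and 276 within number 3. River water replicate 1 belongs to number 1, and without it 99 features passed there. The direction of the change was more alike than the counts. Of the 335 features called from numbers 2 and 3 together, 315 had the same sign within number 1. The corresponding values were 43 of 44 for number 2 and 66 of 68 for number 3, each tested on libraries that took no part in the call. Across all features the share with the same sign was 64.7%, 61.1% and 68.4%, in the order of the numbers.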

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

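The tests of the 20 most abundant features and of an exchanged label were chosen after related results had been seen, and the test of an axis shared by river water replicates 1 and 6 after its own result had been seen.

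River water replicate 1 lay far below its group in similarity, with a median Spearman correlation of 0.956 with the other river water libraries, 843 features more than 2-fold from their mean, and 9019 features detected where the others had 9024 or 9025. Lower depth does not explain its low correlation. With all libraries thinned to the smallest total, its median was 0.955, against 0.988 to 0.995 in the other 17 libraries. With the 20 most abundant features removed and the rest thinned, the values were again 0.955 against 0.988 to 0.995. Fewer counts left for the other features therefore do not explain the low correlation either. A rank correlation hardly responds to the loss of 20 of 9008 features or to a shift in scaling. Whether dominant features contributed to the 843 differences of more than 2-fold was therefore not tested. River water replicate 1 correlated with the laboratory water libraries at 0.937 to 0.955, against 0.991 to 0.997 among those libraries. It was thus not a typical laboratory water pool under an exchanged label. An unusual laboratory water pool with an exchanged label is not excluded. This library correlated at only 0.928 to 0.965 with the libraries of both groups, so the comparison cannot assign its water. A stronger form of the river response stays open: across features, its deviation from 4 of the other river water libraries correlated with the change of the remaining 4 against laboratory water at a median of 0.137 over 70 splits, with a range of -0.119 to 0.424. RNA quality, the stage or tissue makeup of the pool and a sample from outside the 2 groups were not tested and stay open.

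River water replicate 6 had the highest levels of K06244 (56.4 CPM) and K06256 (21.6 CPM), far above the other river water libraries. Of 85 features more than 2-fold higher in replicate 6 than in the mean of the other 7 river water libraries, 54 were more than 2-fold lower in replicate 1, where 6.66 would overlap by chance. With separate baselines, the deviations of the 2 libraries correlated across features at -0.567 (median of 35 splits, range -0.632 to -0.489). A candidate explanation is a single axis along which pools vary in either water: the first principal component of the laboratory water libraries alone correlated with the deviation of replicate 1 at 0.485 and with that of replicate 6 at -0.563. What such an axis reflects was not tested, and no biological explanation was tested.

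Laboratory water replicate 6 had a median Spearman correlation of 0.992 with its group, the lowest of the 9. The series table was also fitted without the low-count filter, over 9645 features. Of its 620 features outside the sample files, 1 passed the test and 44 had an unadjusted p under 0.05 (edgeR). The feature that passed had 86 counts in laboratory water and 163 in river water over 9 columns each (log2 fold change 0.94, adjusted p = 0.0440, edgeR). The gap test for a library far from its group was applied to 17 sets of 9 values and singled out 6, where about 1 in 20 would be by chance. That rate assumes normally distributed values. The numbers of detected features are nearly all tied and the numbers of features more than 2-fold away are skewed, so it is only a rough guide. It also does not hold for K06244 and K06256, which were chosen for their rise in the same libraries. Of the 6, 3 belong to river water replicate 1 and are related measures, and 2 belong to river water replicate 6.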

How the results depend on the processing

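The settings with river water replicates 1 and 6 left out, quality weights, the covariate, the whole series table and the other similarity measures were chosen after the data were examined. Apart from the fits within a file number, none of the 565 features changed direction under any setting of this section in which it was fitted. Those settings reused most or all of the libraries of the main fit, so the kept signs are not separate evidence. In the fits within a file number, 565 kept their sign in numbers 1 and 2 and 564 in number 3. Within number 1 without river water replicate 1, 563 did so. Those libraries also took part in the main fit. The count of 565 moved to 899 with DESeq2, 1225 with limma-voom and quality weights, 1041 with river water replicates 1 and 6 left out, and 1388 with the score of each library on the first laboratory component as a covariate. It fell to 311 when counts were summed within each file number (3 against 3, so fewer samples), and to 46 when a fold change of at least 1.5 was also required. With the replicate number as a replicate block the count was 356 (324 shared with the 565). Deviations from the group means correlated by more than 0.1 in 4 of 9 same-numbered pairs, with values from -0.433 to 0.372. Of the 18 libraries, 2 correlated best with their own number. Most laboratory water libraries matched best with river water replicate 1 or 6, the most deviant libraries. These values therefore neither show nor exclude that the numbers pair the samples. The other 10 settings gave 507 to 624, and leaving out 1 library gave 377 to 979, the highest without river water replicate 1. The share of changed features that were higher was 34.0%, and ranged from 21.5% (summed counts) to 40.1% (covariate). The number of higher features alone fell from 192 to 125, 121 and 119 without laboratory water replicates 2 and 3 and river water replicate 9. K06244, K01298 and K03479 passed in every setting that tested them, including each library left out, with adjusted p of at most 0.0350, 0.0447 and 0.0486. K06256 missed in 3 of 15 settings, with adjusted p of 0.0557 (limma-voom), 0.0526 (limma-voom with correlation within file prefix) and 0.0833 (summed counts, edgeR), against 0.0011 to 0.0321 in the other 12. The median similarity of river water replicate 1, 0.956, became 0.924 among features of at least 10 CPM in 9 libraries, and lay between 0.955 and 0.958 in 3 other measures. The cause was not tested for DESeq2, the quality weights, the replicate block, the libraries left out, K06256 or the similarity. The gene list tests and all their alternatives (estimated correlation, fry, block, summed counts, other scaling, no filter, libraries left out) were not run. The files give no gene names, and no reference table was used. At this depth, and with features drawn independently, the simulation recovered 35.8% of 1.2-fold changes, so most changes of that size were missed there.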

Other observations

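The fit with a covariate and the test of its score were chosen after the data were examined.

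If the libraries are independent, the count of 565 as a whole was far above that of splits drawn without regard to the water. Among 100 splits of the 18 libraries into 9 and 9, 1 gave as many, which was the real split, and the highest count in any other was 2. These splits ignore the file number, so they do not cover the case in which libraries of a number share a tank or family.

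No difference between the waters was detected along the first principal component of the laboratory water libraries, but the test cannot decide whether there is one. The component held 26.8% of the variance in laboratory water. It was fitted to those libraries alone, and the river water libraries were then projected onto it. Scores of the 2 groups are therefore not exchangeable, so the permutation p is approximate and the SDs are not comparable. The mean score was 2.30 higher in river water (SD 12 in river water and 7.85 in laboratory water, n = 9 each, two-sided permutation p = 0.667). This value rests on single libraries. The difference of river from laboratory water was -1.13 without river water replicate 1 (n = 8 and 9, two-sided permutation p = 0.75). It was 4.36 without river water replicate 6 (n = 8 and 9, two-sided permutation p = 0.390). With this score as a covariate the comparison called 1388 features, 557 higher and 831 lower in river water, and all 565 of the original calls were among them. The axis was estimated from laboratory water libraries that also entered the comparison, so part of the rise to 1388 could come from its construction, and this was not tested. A hypothesis is that variation between pools along this axis may hide small differences between the waters.

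River water pools were not shown to be more variable than laboratory water pools. The mean distance of a library from the rest of its group was 0.243 ± 0.157 log2 units in river water and 0.169 ± 0.0177 in laboratory water (SD, n = 9 each, exact two-sided permutation p = 0.118). Without river water replicate 1 the river water mean was 0.182 ± 0.0428 (SD, n = 8, exact permutation p = 0.457), and without replicates 1 and 6 it was 0.168 ± 0.0180 (SD, n = 7, exact permutation p = 0.966).

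Within laboratory water, 88 features differed between the 3 file numbers (edgeR quasi-likelihood test, adjusted p under 0.05), and 3 of 100 partitions of the 9 libraries into trios gave as many, the file number included. The highest count from another partition was 397, several times the real one, while the median of the other partitions was 0. What sets that highest partition apart, and how it relates to the file number, was not examined. Within river water 0 features differed by file number and 165 had an unadjusted p under 0.05 (edgeR). All 100 partitions gave 0 as well, so these counts decide nothing.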
